A study of Mus musculus with 6 samples.

How the data were processed

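Poly(A) RNA from naive CD4+ T cells of mouse spleen was sequenced in 6 libraries, 3 from untreated and 3 from rapamycin-treated wild-type mice. Per the labels' protocols, RNA was extracted with RNAiso PLUS, cleaned with a NucleoSpin column and made into libraries with the NEBNext Ultra II Directional kit. Per the submitters' processing notes, reads were processed with STAR and RSEM against mm10, with no versions given in the sources used here. Per the file headers, each deposited table gives RSEM expected counts, TPM, FPKM, length and effective length for 55487 genes. The authors' expected counts are estimates that divide reads shared between genes, so values need not be whole, and between 25.9% and 29.7% of each library's counts fell on genes whose value was not whole within 0.005. The authors' TPM and FPKM values are scaled for effective length and depth. Gene symbols, positions and transcript GC content came from GENCODE vM21 on GRCm38, the assembly that mm10 names, which matched 55227 of the gene identifiers. The 260 without a match held at most 0.013% of a library's counts.

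Expected counts were rounded to whole numbers. Genes were kept with edgeR's filterByExpr, which left 11950, and scaled with TMM factors. Groups were compared with edgeR's quasi-likelihood test (estimateDisp and glmQLFit, robust, group as the only term), and p-values were adjusted over the tested genes by the Benjamini-Hochberg method, with a threshold of 0.05. The standard error of a log2 fold change was taken as its size over the square root of the test's F. Lists were tested with camera at a preset correlation of 0.01 and, beside it, with an estimated correlation and with fry, and adjusted over 44 lists. Before the data were examined, 46 lists, the groups, the test, its alternatives and the rule for named genes were fixed. The Platelet list had fewer than 5 measured genes and the Sex-linked list was kept as values, so that neither was tested. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9 were used.

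The rule named the 10 genes with the largest and the 10 with the smallest log2 fold change among those past the threshold, with an average log2 CPM of at least 2 and all libraries of one group above all of the other, leaving out receptor and antibody gene segments, predicted genes and pseudogenes. It also named up to 4 members of each list past the threshold by smallest adjusted p, and Mtor, Fkbp1a, Rps6, Cd4, Cd8a, Cd44, Foxp3 and Il2ra. A few genes that the rule named are not reported here. From a list with no such member it named up to 2 by average level.

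The length correction was chosen after seeing the data. For each library, deviations of log2 CPM from the mean of all 6 were fitted with a spline of 5 degrees of freedom on log2 gene length, over genes with an average log2 CPM of at least 2, and the fitted values entered the model as offsets. A further fit added a spline on GC content. The alternatives fixed before were RLE, upper-quartile and no composition factors, no filter and a filter of at least 2 CPM in at least 3 libraries, DESeq2, limma-voom, limma on log2(TPM + 1) and log2(TPM + 0.1), effective-length offsets, the replicate number as a block, library sizes without abundant gene classes, a test against a fold of 1.2, and leaving out each library in turn. Library measures were compared with exact two-sided permutation tests, which cannot go below 0.1 with 3 libraries against 3.

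The procedure was tested on simulated data for this comparison, with 200 changed genes among 11770 that passed the filter. edgeR recovered 47.8% of genes changed by 1.2-fold, 67.2% by 1.5-fold and 92.4% by 2-fold, with 6.12% of its calls on unchanged genes. With a length trend of 0.2 log2 per doubling added, 3187 of the unchanged genes were called among 11785 tested, and 10 after the length correction. Both shifted lists were called, as were 5 lists that shared members with them, and 0 of the 33 lists that shared none. Simulated genes were drawn independently of each other, so this check does not show how often camera calls unshifted lists when genes are correlated. At these depths the floor of 3 counts lay between 0.263 and 0.343 CPM, and counting intervals cover counting error only.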

Results

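Poly(A) RNA was sequenced from naive CD4+ T cells taken from the spleen of wild-type C57BL6/J mice. 3 libraries came from untreated mice and 3 from mice given rapamycin in vivo, an inhibitor of the kinase mTOR. The comparison asks how mTOR inhibition alters the state of these cells. The total expected count per library was 11393300, 10384600 and 9712670 in the untreated group and 9315370, 9014200 and 8757280 in the rapamycin group, so that a floor of 3 counts corresponded to between 0.263 and 0.343 CPM, which are counts scaled to a common library size. Levels are given as CPM, mean ± SD over n = 3 libraries, and log2 fold changes are rapamycin over untreated, ± SE. The labels do not say whether the libraries came from separate mice. Variance between libraries of one group was 1.51 to 1.56 times counting noise, so p-values measure the spread between these libraries, which may be technical.

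With rapamycin Il7r, which encodes a receptor chain for the survival cytokine interleukin 7, rose from 489 ± 22.9 to 863 ± 13.7 CPM. Cd44, a marker of activated and memory T cells, fell from 33.7 ± 2.31 to 10.7 ± 0.185 CPM. The serine synthesis enzyme Phgdh fell from 108 ± 4.37 to 55.6 ± 4.39 CPM. Each of these changes had an adjusted p of at most 7.3e-21 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of 11950 genes tested, 2874 were higher and 2785 lower with rapamycin at an adjusted p under 0.05, and 186 of the higher and 194 of the lower ones changed by at least 2-fold. On principal component analysis the first component held 58.1% of the variance and parted the groups.

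Log2 fold changes followed gene length. Across 9979 genes with an average log2 CPM of at least 2, Spearman's rho with gene length was 0.51 (a correlation across genes, which are not independent replicates). The median log2 fold change ran from −0.31 in the shortest of 10 equal groups of genes to 0.24 in the longest. With a length correction chosen after seeing the data, 2411 genes were higher and 2184 lower, and 3646 of the 5659 genes called without it were called in the same direction and 126 in the opposite one. The balance of calls turned with the scaling, to 2459 higher and 3330 lower with upper-quartile factors and 2470 and 3298 without composition factors. A test on log2(TPM + 1) called 2720 genes higher and 1151 lower, or 70.3% higher against 50.8%, with the median of all genes shifted by 0.10, while offsets from the deposited effective lengths left 1930 higher and 1801 lower. Length-corrected values are given for every gene list tested, and for single genes where the correction ended a call, turned its direction or moved it by over 1.5 times.

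**Figure D1:**
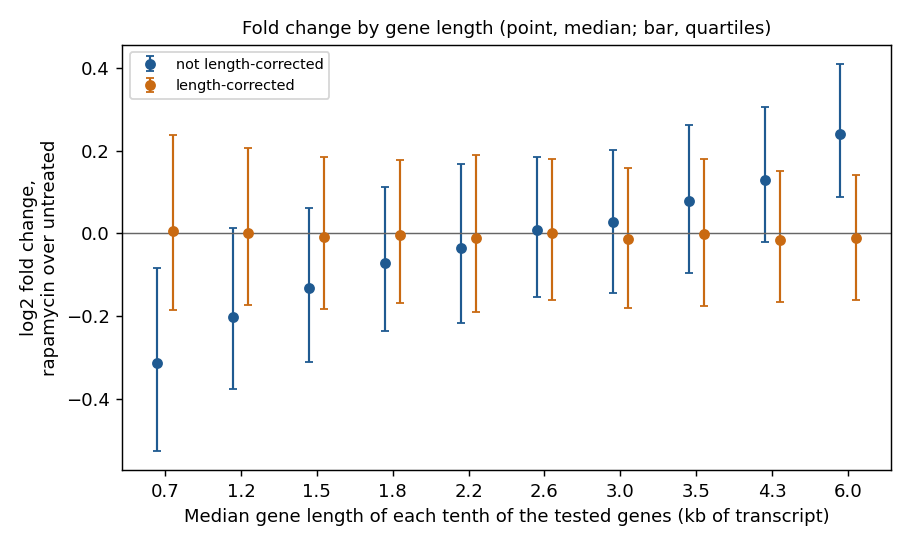
Median log2 fold change of rapamycin over untreated (vertical axis) for 10 equal groups of the 11950 tested genes ordered by gene length (horizontal axis, median length in kb), with bars for the quartiles. Before correction the medians run from −0.31 to 0.24, and after length correction they lie between −0.02 and 0.00.

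Among the genes with the largest rises was Slc15a2, a peptide transporter (ENSMUSG00000022899, mm10 chromosome 16, 36750177 to 36784962), which went from 4.34 ± 1.60 to 43.1 ± 3.35 CPM, a log2 fold change of 3.31 ± 0.13 (adjusted p = 1.1e-24). Cd8a (ENSMUSG00000053977, mm10 chromosome 6, 71373427 to 71379173) rose by 3.09 ± 0.11 from 5.07 ± 0.268 to 43.4 ± 1.25 CPM (adjusted p = 3.3e-32), and Cd8b1, the other CD8 co-receptor chain, rose by 1.66. The giant sarcomere gene Neb rose by 2.60, the transcription factor gene Klf11 by 2.13, the integrin gene Itga7 by 1.56, Capn11 by 1.57, Lzts2 by 1.55 and the histone gene Hist1h2ap by 1.90. Hmga1b rose by 3.10 but is uncertain, since it is a near-identical copy of Hmga1, which changed by −0.50. The counts of Hmga1 and Hmga1b together were 74.4 ± 2.62 CPM in untreated and 67.0 ± 2.77 CPM in rapamycin libraries.

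The genes with the largest falls included several of other blood cells. Ighg2b, an antibody constant region gene (ENSMUSG00000076613, mm10 chromosome 12, 113302965 to 113307933), fell from 17.8 ± 1.71 to 0.381 ± 0.295 CPM, a log2 fold change of −5.52 ± 0.26 (adjusted p = 1.4e-26). Jchain, which joins antibody units, fell by 3.87 on the log2 scale. S100a9 and Lyz2, abundant in neutrophils and macrophages, changed by −2.62 and −2.20, the granzyme gene Gzma by −1.84, the cystatin gene Cst7 by −1.81 and Mpeg1, a macrophage gene, by −1.66. The monocarboxylate transporter gene Slc16a5 fell from 74.6 ± 2.08 to 18.4 ± 0.393 CPM, the AMP deaminase gene Ampd1 changed by −1.96 and Igsf23 by −1.91.

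Of 44 gene lists tested with camera at a preset correlation of 0.01, 8 were higher and 18 lower. The length correction gave 9 higher and 15 lower, and with an estimated correlation 4 were higher and 9 lower. For the lists that stayed called with an estimated correlation, camera's adjusted p then lay between 0.0215 and 0.0428. That of FOXO targets went from 2.4e-14 to 0.0215, and that of cytosolic ribosomal proteins from 5.2e-54 to 0.0256. Camera adjusted p-values below are at the preset correlation unless an estimated one is named. A list is said to be called by camera only, which sets its members against all other genes. With fry, which does not, every tested list except erythroid genes (fry adjusted p = 0.0985) had an adjusted p under 0.05. Among those that camera did not call, fry's adjusted p was 0.0124 for the mTOR pathway and 0.0281 for cell cycle genes. In each list, counts of genes called are over all genes tested unless said to be adjusted over the list alone.

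**Figure D2:**
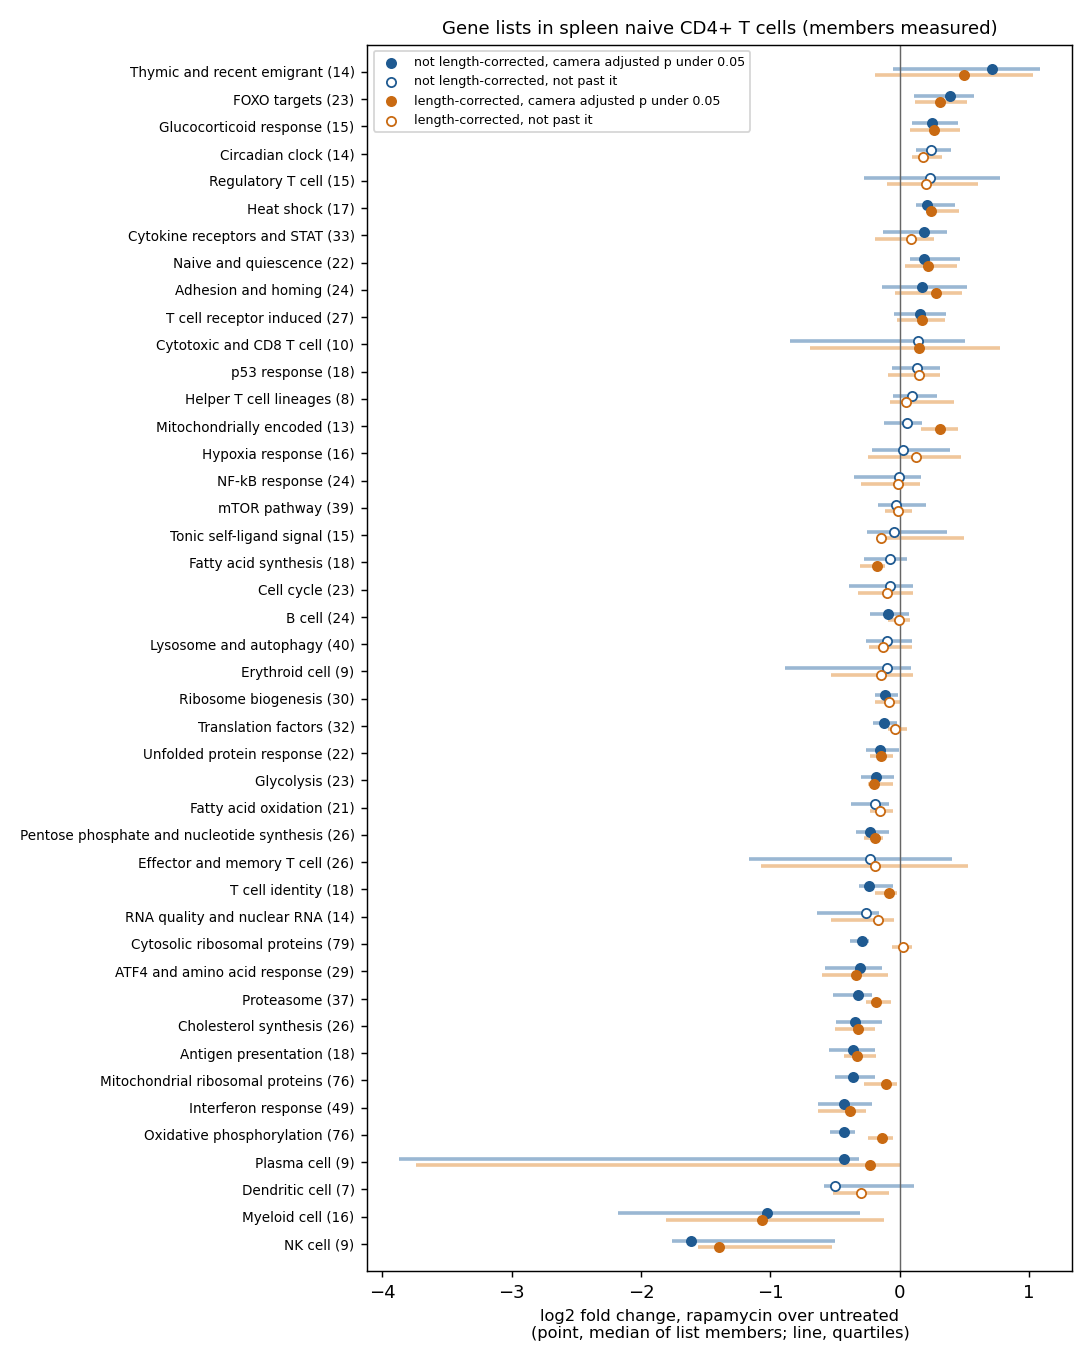
Median log2 fold change of rapamycin over untreated (horizontal axis) for the members of each of the 44 gene lists (vertical axis, with the number measured), before and after length correction, with lines for the quartiles. Filled points pass camera's adjusted p under 0.05 and open points do not. FOXO targets lie at 0.39 before and 0.31 after correction, and cytosolic ribosomal proteins at −0.29 and 0.02.

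FOXO target genes, which FOXO transcription factors induce when growth factor signalling is low, rose together. Of 23 measured, 17 rose and 1 fell (adjusted over the list alone, 17 higher and 1 lower), with a median of 0.39 (length-corrected 0.31) and a camera adjusted p of 2.4e-14. Il7r rose by 0.82 ± 0.02 and Klhl24 by 0.80 ± 0.03. Rictor, a component of mTOR complex 2, rose by 0.67 (length-corrected 0.32). In the list of naive and quiescence genes 17 of 22 rose and 4 fell (adjusted over the list alone, 17 higher and 4 lower), with a median of 0.18 (length-corrected 0.22) and a camera adjusted p of 3.2e-08, or adjusted p = 0.0539 with an estimated correlation. Peli1, a ubiquitin ligase gene, rose by 0.59 and Bach2, a transcription factor gene that restrains effector differentiation, by 0.76 (length-corrected 0.47). Adhesion and homing genes were higher as a list (14 of 24 rose and 7 fell; adjusted over the list alone, 15 higher and 7 lower), with a median of 0.17, a length-corrected median of 0.28 and a camera adjusted p of 1.7e-04. The chemokine receptor gene Cxcr4 rose by 1.51 ± 0.06, the integrin gene Itga4 by 0.81 (length-corrected 0.45) and Rasgrp2, a guanine nucleotide exchange factor gene, by 0.51. Cxcr4, Il7r and Txnip, whose rise was 0.39, also belong to the list of glucocorticoid-induced genes, as does Ddit4, which fell by 0.84 on the log2 scale. In that list 11 of 15 rose and 3 fell (adjusted over the list alone, 11 higher and 3 lower; median 0.25, length-corrected 0.27, camera adjusted p = 5.4e-05).

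Effector and memory genes moved in both directions. 13 of 26 fell and 9 rose (adjusted over the list alone, 10 higher and 13 lower), and the list was not called, with a median of −0.23 (length-corrected −0.19) and a camera adjusted p of 0.106. Cd44 fell by 1.65 on the log2 scale, the LIM protein gene Crip1 changed by −1.53 and the intermediate filament gene Vim by −0.98, while the scaffold gene Ahnak rose by 1.22 (length-corrected 0.70). In the same libraries the median was −1.03 for myeloid and −1.61 for NK cell markers. Genes of T cell identity fell as a list, 13 of 18 lower and 2 higher (adjusted over the list alone, 2 higher and 13 lower), with a median of −0.24, a length-corrected median of −0.09 and a camera adjusted p of 3.2e-08. The receptor constant gene Trac changed by −0.80 (length-corrected −0.52), Trbc1 by −0.41 (length-corrected −0.08), Thy1 by −0.60 and the kinase gene Lck by −0.30 (length-corrected −0.18). Cd4 itself was 716 ± 11.6 CPM in untreated and 687 ± 9.29 CPM in rapamycin libraries, a log2 fold change of −0.06 ± 0.02 whose adjusted p of 0.0158 was lost without untreated replicate 3 (−0.05) or rapamycin replicate 2 (−0.05). Early genes of T cell receptor signalling rose as a list, 11 of 27 higher and 5 lower (adjusted over the list alone, 13 higher and 5 lower; median 0.15, length-corrected 0.17). The camera adjusted p was 0.0222, or adjusted p = 0.285 with an estimated correlation. Nr4a1 rose by 0.55, Tagap by 0.64, Jun by 0.29 and Fos by 0.25. Of 15 genes tied to tonic self-ligand signals, 4 rose and 5 fell (the same adjusted over the list alone; median −0.05, length-corrected −0.14, camera adjusted p = 0.193), with Nr4a1 at 0.55, Ly6a at −1.43, Ly6c1 at −1.23 and Cd6 at −0.31.

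**Figure D3:**
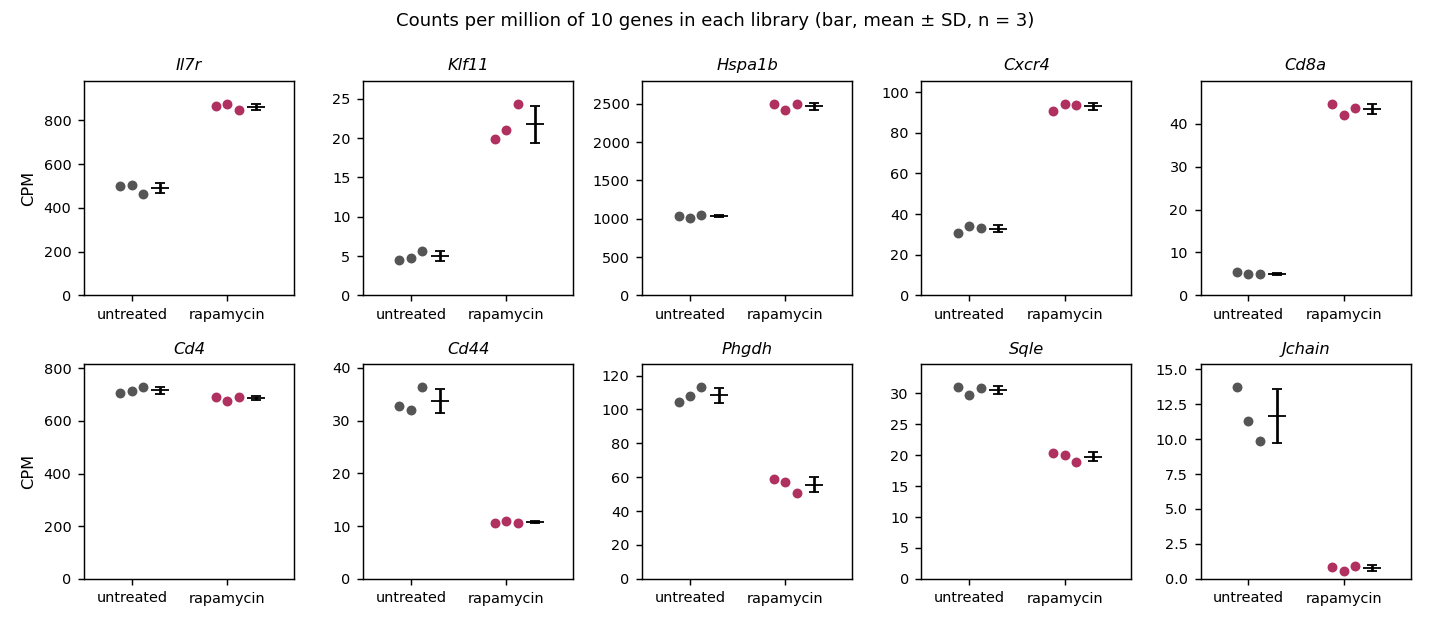
CPM (vertical axis, from 0) of 10 genes in each of the 6 libraries, by group, with the mean and SD beside the points. Il7r, Klf11, Hspa1b, Cxcr4 and Cd8a are higher in all 3 rapamycin libraries, Cd44, Phgdh, Sqle and Jchain are lower in all 3, and Cd4 lies at 716 ± 11.6 CPM in untreated and 687 ± 9.29 CPM in rapamycin libraries.

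Amino acid synthesis and tRNA charging genes of the ATF4 response fell. Of 29 measured, 22 fell and 2 rose (adjusted over the list alone, 2 higher and 23 lower), with a median of −0.31 (length-corrected −0.34) and a camera adjusted p of 4.4e-08. Phgdh changed by −0.96 ± 0.05, the mitochondrial folate enzyme gene Mthfd2 by −0.93 ± 0.08, the alanyl-tRNA synthetase gene Aars by −0.87 ± 0.06 and Ddit4, an inhibitor of mTOR complex 1, by −0.84 ± 0.05. Cholesterol synthesis genes fell as a list, 16 of 26 lower and 1 higher (the same adjusted over the list alone), with a median of −0.35 (length-corrected −0.32). The camera adjusted p was 0.00391, or adjusted p = 0.0580 with an estimated correlation. Sqle, squalene epoxidase, fell from 30.5 ± 0.670 to 19.8 ± 0.764 CPM, Fdps changed by −0.57 and Msmo1 by −0.65. Fatty acid synthesis genes were 6 lower and 3 higher of 18 (the same adjusted over the list alone; median −0.08, camera adjusted p = 0.106), and became a called list after length correction (median −0.18, adjusted p = 5.9e-04). The desaturase gene Scd2 changed by −0.79, Acsl5 by −0.58 and Srebf1 by −0.37, and Acss2 rose by 0.25. Of 21 fatty acid oxidation genes 9 fell (the same adjusted over the list alone), among them Acadvl (−0.42), Acaa2 (−0.36, length-corrected −0.24) and Etfb (−0.62, length-corrected −0.32), and 1 rose, Cpt1a, the gate of fatty acid entry into mitochondria, by 0.98. The list had a median of −0.19 (length-corrected −0.16, with 4 lower and 1 higher) and a camera adjusted p of 0.161.

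Glycolysis genes fell as a list, 14 of 23 lower and 2 higher (the same adjusted over the list alone; median −0.19, length-corrected −0.20). The camera adjusted p was 0.00185, or adjusted p = 0.0713 with an estimated correlation. The lactate dehydrogenase gene Ldha changed by −0.46, Aldoa by −0.40 (length-corrected −0.26), Gapdh by −0.31 (length-corrected −0.12) and Pkm by −0.21. Of 26 pentose phosphate and nucleotide synthesis genes, 14 fell and 1 rose (adjusted over the list alone, 1 higher and 15 lower; median −0.23, length-corrected −0.19), with Tkt at −0.31, Mthfd1 at −0.38, Pgls at −0.50 (length-corrected −0.26) and Taldo1 at −0.37 (length-corrected −0.17). The camera adjusted p was 0.00262, or adjusted p = 0.0569 with an estimated correlation. Nuclear genes of oxidative phosphorylation fell in 74 of 76 cases (adjusted over the list alone, 0 higher and 75 lower), with a median of −0.43 that shrank to −0.14 with the length correction (camera adjusted p = 3.7e-16 and 3.9e-04), after which 34 were lower and 1 higher. The ATP synthase genes Atp5e and Atp5a1 changed by −0.78 (length-corrected −0.35) and −0.28, Uqcrfs1 by −0.62 and Cox4i1 by −0.37 (length-corrected −0.05, not called). Genes encoded in the mitochondria were 7 higher and 3 lower of 13 (the same adjusted over the list alone), with a median of 0.05 and a camera adjusted p of 0.805. After length correction 10 were higher and 0 lower, with a median of 0.31 (adjusted p = 5.7e-07). mt-Nd5 rose by 0.22 and mt-Nd4 by 0.18 (length-corrected 0.33), while mt-Nd1 changed by −0.12 and turned to 0.13 with the correction, as mt-Nd6 turned from −0.29 to 0.10.

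Genes of the translation machinery were lower, and this depended on gene length. Of 79 cytosolic ribosomal protein genes, 78 fell (the same adjusted over the list alone), with a median of −0.29 (camera adjusted p = 5.2e-54). The length correction left a median of 0.02, with 33 members higher, 22 lower and an adjusted p of 0.435, since the median member is 655 bases long. Rps20 went from −0.57 to −0.26, Rpl37a from −0.57 to −0.20, Rps12 from −0.51 to −0.14 and Rps6, a substrate of the mTOR pathway, from −0.31 to −0.03, not called, while Rpsa went from −0.34 to −0.18. Their share of all counts was 11.2 ± 0.029% in untreated and 8.96 ± 0.064% in rapamycin libraries, with an exact two-sided permutation p of 0.1, the smallest 3 against 3 libraries can give. Translation factors fell as a list (21 of 32 lower, 6 higher; adjusted over the list alone, 6 higher and 22 lower; median −0.13, camera adjusted p = 5.0e-04) and were not called after length correction (12 lower and 8 higher, median −0.04, adjusted p = 0.272). Eif3f changed by −0.39, Rack1 by −0.32 (length-corrected −0.16), the elongation factor gene Eef1a1 by −0.15 (length-corrected −0.05) and Eif4ebp2 rose by 0.29 (length-corrected 0.06). Ribosome biogenesis genes had 15 of 30 lower and 3 higher (adjusted over the list alone, 3 higher and 16 lower), among them Fbl at −0.39 (length-corrected −0.19), Npm3 at −0.59 (length-corrected −0.31), Polr1a at 0.30 (length-corrected 0.08, not called) and Npm1 at −0.12 (length-corrected 0.02, not called). The list's median was −0.11 with a camera adjusted p of 0.0481, which became 0.0656 after length correction (median −0.09), adjusted p = 0.135 with an estimated correlation. The call was lost without untreated replicate 3 (median −0.10), rapamycin replicate 1 (−0.11) or rapamycin replicate 2 (−0.11). In all it was lost under 13 of 22 alternatives, and the median turned to 0.02 with log2(TPM + 1). Mitochondrial ribosomal protein genes had 52 of 76 lower (adjusted over the list alone, 0 higher and 56 lower; median −0.36, camera adjusted p = 1.0e-05), with Mrpl11 at −0.83, Mrps16 at −0.74, Mrpl52 at −0.92 (length-corrected −0.48) and Mrps34 at −0.68 (length-corrected −0.42). After length correction 18 were lower and 3 higher (median −0.10, adjusted p = 0.0459, or adjusted p = 0.0870 with an estimated correlation).

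Interferon-stimulated genes fell. 36 of 49 measured were lower and 7 higher (adjusted over the list alone, 7 higher and 37 lower), with a median of −0.43 (length-corrected −0.39) and a camera adjusted p of 5.7e-09. Ly6a changed by −1.43 ± 0.07, the guanosine triphosphatase gene Igtp by −0.63 ± 0.04 and the transcription factor gene Irf1 by −0.53 ± 0.03. Antigen presentation genes fell in 17 of 18 cases (the same adjusted over the list alone; median −0.36, length-corrected −0.33, camera adjusted p = 9.6e-18), among them H2-T22 at −0.76 and B2m, the light chain of class I molecules, at −0.40 (length-corrected −0.12). The median in the same libraries was −1.03 for myeloid and −0.09 for B cell markers. Proteasome genes fell in 31 of 37 cases (adjusted over the list alone, 1 higher and 32 lower; median −0.32, length-corrected −0.18, camera adjusted p = 4.0e-13). The interferon-inducible subunit genes Psmb8, Psmb9 and Psmb10 changed by −0.62 (length-corrected −0.40), −0.79 and −0.86, and the activator gene Psme1 by −0.51 (length-corrected −0.28). Cytokine receptor and STAT genes were higher as a list (18 of 33 rose, 9 fell; adjusted over the list alone, 20 higher and 9 lower; median 0.19, camera adjusted p = 0.0147). The call was lost with the length correction (median 0.09, adjusted p = 0.432) and gave adjusted p = 0.0943 with an estimated correlation. The survival gene Bcl2 rose by 0.98 and the kinase gene Pim1 by 0.94, while Jak3 changed by −0.78.

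Heat shock genes rose. 12 of 17 were higher and 1 lower (adjusted over the list alone, 13 higher and 1 lower), with a median of 0.21 (length-corrected 0.24) and a camera adjusted p of 2.4e-14. Hspa1b, an inducible Hsp70 gene, went from 1034 ± 15.4 to 2469.8 ± 45.8 CPM (1.26 ± 0.02), its near-identical neighbour Hspa1a changed by 1.36 ± 0.03, so that the split between them is uncertain, Dnajb1 rose by 0.70 and Hsph1 by 0.71. Genes of the unfolded protein response fell as a list (13 of 22 lower, 2 higher, the same adjusted over the list alone; median −0.16, length-corrected −0.14), with Pdia3 at −0.30, Hspa5 at −0.23 and Sec61b at −0.43 (length-corrected −0.05, not called), while Hsp90b1 rose by 0.18. The camera adjusted p was 0.0278, or adjusted p = 0.167 with an estimated correlation.

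Genes of the mTOR pathway itself went both ways. 13 of 39 rose and 10 fell (adjusted over the list alone, 13 higher and 11 lower), with a median of −0.03, a mean of 0.03, an upward test direction and a camera adjusted p of 0.420 (length-corrected median −0.01). Sesn1 rose by 0.52, Tsc1 by 0.50 (length-corrected 0.24) and Mtor by 0.30 (length-corrected 0.02, not called). Fkbp1a, which encodes the protein that binds rapamycin, changed by −0.13 (length-corrected 0.03, not called), and the call was lost without rapamycin replicate 1 (−0.11). Lysosome and autophagy genes had 8 of 40 higher and 17 lower (the same adjusted over the list alone; median −0.10, length-corrected −0.13, camera adjusted p = 0.221), with Wipi2 at 0.54, Neu1 at 0.42, Ctsb at −0.34 and Atp6v0c at −0.42 (length-corrected −0.24).

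Markers of other cell types moved apart. In the myeloid list 11 of 16 fell and 1 rose (the same adjusted over the list alone; median −1.03, length-corrected −1.07, camera adjusted p = 0.00148, or adjusted p = 0.0569 with an estimated correlation), with Lyz2 going from 17.1 ± 1.26 to 3.71 ± 0.217 CPM and Csf3r, the receptor of a neutrophil growth factor, at −1.65 and Ctss at −0.36 (length-corrected −0.20), and the list's median was −0.64 without untreated replicate 2 and −0.59 without untreated replicate 3. Plasma cell markers had 5 of 9 lower and 1 higher (adjusted over the list alone, 1 higher and 6 lower; median −0.44, length-corrected −0.23, camera adjusted p = 0.00116, or adjusted p = 0.0569 with an estimated correlation), and the member that rose was Prdm1 (1.07), which activated T cells also express. Igha had 5.68 ± 0.40 CPM in untreated and 0.113 ± 0.195 CPM in rapamycin libraries, whose counts were 0, 3 and 0. NK cell markers had 7 of 9 lower (adjusted over the list alone, 1 higher and 7 lower; median −1.61, length-corrected −1.40, camera adjusted p = 0.0445, or adjusted p = 0.154 with an estimated correlation), and the call was lost without untreated replicate 2 (median −0.82) or untreated replicate 3 (−1.11), while Klrb1c changed by −1.63 and the signalling adaptor gene Tyrobp, also a myeloid marker, by −1.76. B cell markers had 10 of 24 lower (the same adjusted over the list alone; median −0.09, or −0.15 without rapamycin replicate 3 and 0.01 with log2(TPM + 1), camera adjusted p = 0.0154, or adjusted p = 0.260 with an estimated correlation) and were not called after length correction (4 lower and 3 higher, median −0.01, adjusted p = 0.332), with Ighm at −0.58, Igkc at −0.65 (length-corrected −0.26), Cd74 at −0.16 (length-corrected 0.04, not called) and Cd79b at −0.28 (length-corrected −0.09, not called). Cytotoxic and CD8 T cell markers had 3 higher and 3 lower of 10 (adjusted over the list alone, 4 higher and 3 lower; median 0.14, camera adjusted p = 0.230, length-corrected median 0.15 and adjusted p = 0.0317, or adjusted p = 0.128 with the correction and an estimated correlation), with Cd8a at 3.09, Cd8b1 at 1.66, the protease gene Ctsw at −0.91 and Gzma at −1.84. Thymic and recent emigrant genes, to which Cd8a and Cd8b1 belong, rose as a list (8 of 14 higher and 2 lower, the same adjusted over the list alone; median 0.72, length-corrected 0.49 with 8 higher and 4 lower), with Cd55 at 0.77 and Nt5e at 0.79. The camera adjusted p was 8.6e-05, or adjusted p = 0.0580 with an estimated correlation. Regulatory T cell markers were not called as a list (6 higher, 3 lower of 15, the same adjusted over the list alone; median 0.23, length-corrected 0.20 with 5 higher and 0 lower, camera adjusted p = 0.519). The integrin gene Itgae rose by 2.59 ± 0.39 and Nrp1 by 2.27 ± 0.37, Izumo1r changed by −0.33 (length-corrected −0.14, not called), whereas the lineage factor Foxp3 had 1.63 ± 0.663 and 1.91 ± 0.101 CPM (adjusted p = 0.632) and Il2ra 1.94 ± 0.897 and 3.12 ± 0.559 CPM (adjusted p = 0.0783), past the threshold only without untreated replicate 1 (log2 fold change 1.11).

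The remaining lists were not called by camera. Cell cycle genes had 3 higher and 7 lower of 23 (the same adjusted over the list alone; median −0.08, length-corrected −0.10, camera adjusted p = 0.483), with Stmn1 at 0.47, Mcm7 at 0.34, Cdk6 at 0.96 and Cdk4 at −0.44 (length-corrected −0.28). NF-kB genes had 7 higher and 7 lower of 24 (adjusted over the list alone, 8 higher and 8 lower; median −0.01, length-corrected −0.02, camera adjusted p = 0.992, with camera pointing down and fry up), with Bcl3 at −0.95, Traf1 at 0.42, Cflar at 0.28 and Ltb at 0.16 (length-corrected 0.36). Helper T cell lineage genes had 3 higher and 1 lower of 8 (the same adjusted over the list alone; median 0.09, length-corrected 0.05, camera adjusted p = 0.346), with Stat4 at 0.60, Rora at 0.83 (length-corrected 0.54), Gata3 at 0.18 (length-corrected 0.13, not called) and Tbx21 at −1.21. The call of Gata3 was lost without untreated replicate 2 (0.11) or rapamycin replicate 1 (0.16), and that of Tbx21 without untreated replicate 3 (−1.06) or rapamycin replicate 3 (−0.86). Hypoxia genes had 5 higher and 5 lower of 16 (the same adjusted over the list alone; median 0.02, length-corrected 0.12, camera adjusted p = 0.909), with Ddit4 at −0.84, Mxi1 at 0.70, Kdm3a at 0.46 and Ndrg1 at 0.86. p53 targets had 8 higher and 1 lower of 18 (the same adjusted over the list alone; median 0.14, length-corrected 0.15 with 8 higher and 3 lower, camera adjusted p = 0.162), with Mdm2 at 0.31, Phlda3 at 3.03 and Trp53inp1 at 0.26 (length-corrected 0.05, not called). Phlda3 lay near the floor in untreated libraries, at 0.26, 0.57 and 0.31 CPM, against 2.07, 2.59 and 4.87 CPM in rapamycin libraries. Dendritic cell markers had 1 higher and 4 lower of 7 (the same adjusted over the list alone; median −0.50, length-corrected −0.30, camera adjusted p = 0.420), with the chemokine receptor gene Ccr9 at 1.19, Irf8 at −0.50, Naaa at −0.57 and Bst2 at −0.60 (length-corrected −0.30). Erythroid genes had 1 higher and 2 lower of 9 (the same adjusted over the list alone; median −0.10, length-corrected −0.14, camera adjusted p = 0.40), with Hbb-bs at −2.46, Hba-a2 at −1.64 (−1.08 without rapamycin replicate 3) and the spectrin gene Sptb at 1.13.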

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

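All tests in this part were chosen after the result they measure was seen, except the tests of effective lengths, of the genes outside the lists and of other splits of the libraries, which were written before.

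The deposited effective lengths, which entered the comparisons only as an alternative, differed between groups. The median of length minus effective length over genes longer than 3000 bases, which follows the mean fragment length in RSEM's model, was 239.6 ± 0.37 bases in untreated and 254.0 ± 3.1 bases in rapamycin libraries, a difference of 14.4 bases with every rapamycin library above every untreated one (exact two-sided permutation p = 0.1, the smallest 3 against 3 can give).

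The dependence of fold change on gene length was weighed first. If it came only from the fragment lengths that RSEM modelled, offsets from the effective lengths would remove it, but Spearman's rho across 9979 genes was 0.46 with them against 0.51 without. It was not carried by the short gene classes of the lists alone, since rho was 0.50 over the 9024 genes outside them. The slope of log2 CPM per doubling of gene length was 0.18 higher in rapamycin than in untreated libraries and differed by at most 0.0058 within a group. Separate preparation or handling of the groups may give such a step, a response of the cells to rapamycin may too, and these cannot be told apart because every library of a group shares both.

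The small spread between libraries of one group was weighed next. If one library per group had been sequenced 3 times, variance over counting noise would be near 1, provided that reads were counted independently. Its lowest value over the 6 pairs was 1.51. Among genes with 20 to 200 counts in a pair the ratio was already 1.46 to 1.54. Whether reads were independent was not tested, so the ratio cannot exclude repeated sequencing of one library. One pool of cells or RNA behind each group is a candidate explanation, because the ratio stayed at or below 1.82 among genes with 2000 or more counts in a pair, where differences between mice would add most. The labels do not settle it, and if it holds the p-values say nothing about variation between mice.

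Cell type markers were weighed last. A lower share of all other cells in the rapamycin samples would move B cell and myeloid markers alike if both came from such cells alone. The median log2 fold change of 24 B cell markers exceeded that of 16 myeloid markers by 0.94 (quartiles −0.23 to 0.07 and −2.17 to −0.31, permutation p = 8e-05 over 100000 resamples). The permutation shuffled genes between the lists, and genes are not independent replicates. Which cells the marker counts came from was not measured. The test therefore cannot exclude a lower share of other cells. The myeloid median was −0.64 without untreated replicate 2 and −0.59 without untreated replicate 3, where the difference was not tested again, and of the B cell and myeloid markers 0 and 4 are also in another list. Cd74 had 668 ± 8.29 and Lyz2 17.1 ± 1.26 CPM in untreated libraries, and a sort for naive CD4+ T cells would remove both cell types. CD8 T cells, which such a sort would remove too, in the rapamycin samples could give the rise of Cd8a and Cd8b1, which gained 38.3 and 31.8 CPM, a ratio of 1.21, and this stays open, because the other 8 members of the list went both ways, from −1.84 to 0.55 with a median of −0.33. The lowest of these 8, Gzma, is also in the NK cell list, whose median was −1.61, so they do not weigh CD8 T cells alone. A change in the cells of the rapamycin-treated mice is open too and was not tested.

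With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 2874 higher and 2785 lower genes, and the highest of the other splits gave 1 in either direction, with 1 split of the 10 reaching the real count in each. For the lists the real split gave 8 higher and 18 lower. Each other split was counted by the larger of its 2 directions, since its sides have no order. So counted, the highest other was 14, and 9 and 1 of the 10 splits, the real one included, reached 8 and 18. The 9 thus sets the smaller side of the real split against the larger side of each other, and does not weigh the higher lists evenly. The other splits keep 2 libraries of one group on a side and so hold part of the contrast.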

How the results depend on the processing

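Alternatives were fixed before the data were examined except the length and GC corrections, which were chosen after. Of 178 genes named by the rule, 126 kept their direction and side of the threshold under every alternative that gave them a value. Of the 44 lists 22 kept their side of the threshold and, where called, their direction, while medians of several lists not called changed sign. Among called lists the median also changed sign for cytosolic ribosomal proteins, ribosome biogenesis and B cell markers. Their highest medians over the alternatives were 0.021, 0.018 and 0.015. The stricter filter gave a value for 175 of these genes and the fit without abundant gene classes for 162. The count of higher genes ranged over 2579 to 2698 and of lower genes over 2486 to 2562 when one library was left out, and higher lists stayed at 8 and lower lists lay between 16 and 18. Library measures kept their sign without any one library, with differences between −1860000 and −1019680 for the total count, −604.5 and −424 for genes detected, −1.11 and −1.09 for the percent of the 100 top genes, 0.069 and 0.089 for the mitochondrial percent, −2.31 and −2.25 for the ribosomal protein percent, −0.00077 and −0.00061 for the haemoglobin percent and −0.042 and −0.041 for the immunoglobulin percent. A test against a fold of 1.2 left 990 higher and 894 lower genes, since it asks for a larger change, and gives no list test. Lower genes numbered 1151 with log2(TPM + 1), 1137 with log2(TPM + 0.1), where the median of all genes shifted by 0.11, and the cause was not tested. Effective-length offsets left 1930 higher and 1801 lower genes, and the cause was not tested. An estimated correlation left 4 higher and 9 lower lists, and with the length correction as well 7 and 9. What in that form of the test lowered the counts was not examined. DESeq2 called 2417 higher and 2100 lower genes. Without a filter 2612 genes were higher and 2914 lower, so that lower calls exceeded higher ones, as with upper-quartile factors (2459 and 3330) and without composition factors (2470 and 3298). With the replicate block, 2850 genes were higher, 2743 lower and 8 and 18 lists were called. The replicate numbers gave no sign of pairing. Same-numbered libraries correlated by −0.06, −0.03 and −0.06 in their deviations from the group means, and 0 of 6 correlated best with their own number. Pairing cannot be excluded this way, because variance within groups was only 1.51 to 1.56 times counting noise, so the deviations are largely counting error. For lists the direction here is that of the test and not of the median, and only cases where either fit made a call are counted. Directions that turned were, with the length correction, the list of cytosolic ribosomal proteins (0.0206, and 0.0206 with an estimated correlation), Npm1 (0.0246), mt-Nd6 (0.0998), mt-Nd1 (0.133), Cd74 (0.0390), Malat1 (−0.0446) and Fkbp1a (0.0289). With length and GC they were the same list (0.0181), mt-Nd6 (0.0159), mt-Nd1 (0.0710), Cd74 (0.0545), Malat1 (−0.0736) and Fkbp1a (0.0398), and with log2(TPM + 1) and log2(TPM + 0.1) Fkbp1a (0.0842 and 0.0847). The cause of these was not tested beyond the length trend that the correction removes by construction. Calls of lists lost most often were those of ribosome biogenesis (13 of 22 alternatives), NK cell (8), B cell (7) and the unfolded protein response (6). Depth limits genes near the floor of 3 counts.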

Other observations

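Several further groups were measured. Clock genes, whose levels follow the time of day, had 8 of 14 higher and 2 lower (adjusted over the list alone, 9 higher and 2 lower; median 0.24, length-corrected 0.18 with 5 higher and 2 lower, camera adjusted p = 0.193), with Nr1d2 at 0.58, Arntl at 0.40, Clock at 0.40 (length-corrected 0.09, not called) and Per1 at 0.27 (length-corrected 0.13, not called). Nuclear RNAs and histone genes that follow RNA quality had 2 of 14 higher and 5 lower (the same adjusted over the list alone; median −0.26, length-corrected −0.17, camera adjusted p = 0.346), with Hist1h2ap at 1.90, Rn7sk at −1.07 (length-corrected −0.59), Neat1 at −0.27 and Malat1 at 0.22, which turned to −0.04 with the length correction. Annotated ribosomal RNA genes held 0.186 ± 0.003% of counts in untreated and 0.0742 ± 0.00039% in rapamycin libraries (exact two-sided permutation p = 0.1, the smallest possible). Of 3 platelet genes measured, 2 were higher (the same adjusted over the list alone; median 0.33, length-corrected 0.10), Itgb3 at 0.33 (length-corrected 0.10) and Itga2b at 0.80, whose call was lost without untreated replicate 2 (0.56) or rapamycin replicate 2 (0.69). Of the Y-linked genes, Eif2s3y changed by −0.88 ± 0.06 while Ddx3y rose by 0.23 (length-corrected 0.10) and Uty by 0.38 (length-corrected 0.25), and Kdm5d had a value of 0.10 (adjusted p = 0.0647, length-corrected −0.07), so that of 4 sex-linked genes measured 2 rose and 1 fell (adjusted over the list alone, 3 higher and 1 lower; median 0.16, mean −0.04, length-corrected median 0.02).

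A few loci were at or near 0 in one group, and were chosen after their values were seen. The processed pseudogene Gm33707 (ENSMUSG00000102298, mm10 chromosome 3, 60769887 to 60770455) had 0 counts in each untreated library and 210, 196 and 191 in the rapamycin libraries, which is at least 77.1-fold higher against a floor of 3 counts per library. The long non-coding RNA Gm2682 (ENSMUSG00000115681, mm10 chromosome 15, 60120540 to 60187408) had 3, 10 and 5 counts in the untreated and 987, 987 and 933 in the rapamycin libraries. Gm42047 (ENSMUSG00000110631, mm10 chromosome 8, 121833247 to 121841178) had 3, 4 and 0 counts against 849, 807 and 806. The processed pseudogene Gm9825 had 2, 2 and 7 counts against 140, 131 and 184. In the other direction Ighg2b, given above among the largest falls, had 183, 199 and 184 counts in the untreated and 1, 3 and 6 in the rapamycin libraries. The labels give the strain C57BL6/J for both groups, but whether the mice were of one colony and all libraries were aligned with the same settings was not given in the sources used here. The counts of all of these loci are therefore uncertain as an effect of rapamycin.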
